A study of Brassica napus with 4 samples.

How the data were processed

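The study measured leaf RNA of 1-month-old Brassica napus seedlings, 1 nontransgenic and 3 transgenic samples, on 4 arrays of 1 slide, so no slide or scan batch could be separated. Per the labels, 20 plants per genotype were grown at a spacing of 50 cm with 14 h of light and 10 h of dark at 28 °C, and total RNA was extracted with a column kit. The sample labels give 3, 4, 5 and 6 plants per sample, whereas the design text gives 3 for each, and this difference was not resolved. Samples were grouped by their genotype labels, which are wild type for the nontransgenic sample and csRRM2 transgenic for the other 3. The name A1 shared by A1-3 and A1-5 is not explained in the labels.

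Per the file headers, the authors' scanner files hold spot intensity values from Agilent Feature Extraction 10.7.1.1, a version the submitters' processing notes also name. They give the mean signal, the local background and a background-corrected processed signal of each of 45220 spots, of which 1417 are control spots. The authors also deposited a series matrix of log2 values. It matched log2 of the quantile-normalized processed signals of all spots to within 5e-09, so its scale is log2 and it is not centred. The median of each of its columns was 7.43.

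Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged, leaving 43603 gene probes. For the main analysis, each array's 75th percentile of log2 processed signal was subtracted. A total of 44 probes without a value on every array were left out. Probes well above background on at least 1 of the 4 arrays were tested, 34827 in all. Signals over background set the precision, and saturated spots were kept. For a probe not well above background on any array of a group, the fold was given as a bound. The bright group's mean was set against the mean, per array, of the higher of the lowest normalized signal among probes well above background and the dim probe's own value. A p-value printed beside a bound tests the full log2 difference and not the bound. For lower transcripts given as a bound, it rests on the spread of signals not well above background.

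Differences between groups were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, all from the transgenic arrays, and 1.62 prior degrees of freedom. The single control was assumed to vary like the transgenic samples. The 32 gene lists covered growth, wall, hormone, photosynthesis, translation, stress, metabolism and tissue marker genes and were matched on gene names in the descriptions. All 32 had at least 5 tested probes and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 32 lists. Camera compares a list with the other probes, while fry asks whether the probes of a list move, on balance, in one direction, and its mixed test asks whether they move in any direction. Words found in 20 to 500 named probes were tested by one-sided Fisher's exact test.

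Gene names came from the descriptions in the scanner files, which can be old. For assembled transcripts they are the name of the best match, which can be in another species. None of the probes matched the RefSeq gene table given, 101 carried a gene symbol and 8762 had a description that names a gene or protein. Of the rest, 16845 had only the name of a sequence library and 10757 had no description. Named genes were chosen by a rule fixed before the data were examined. With 1 probe per identical symbol or description, they are the 10 largest log2 differences in each direction among named probes that passed, lay on the same side of the control in all 3 transgenic samples and were well above background in the whole higher group. Open places were filled by the lowest p. For each list described, up to 2 members above and 2 below the control with the lowest p were available, and all FCA probes were included.

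The fit was tested on simulated data with 200 changed probes among 34827 in each of 10 runs. It recovered 82.5% of 16-fold, 5.37% of 4-fold and 0.152% of 2-fold changes, of which each run held 66 or 67, with 6.4 false calls per run on average. Changes were placed only on probes of intermediate mean level, with no floor, and the simulated control varied like the transgenic arrays. Calls at background are thus not covered. Simulated arrays without any change gave 0.1 calls on average. Alternatives fixed before the data were examined covered normexp background correction with an offset of 50, quantile and median normalization, the series matrix, the filter on dim probes, the variance model, averaging the A1 samples, 1 probe per gene, a 2-fold minimum and leaving out each transgenic sample. Alternatives added afterwards left out saturated probes, scaled on 4 spike-in probes, or replaced local backgrounds above 50 by the array's median before normexp. Figures were drawn with matplotlib.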

Results

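Leaf RNA of 1-month-old seedlings of Brassica napus, the oilseed rape plant, was labelled and hybridised to a 1-colour Agilent oligonucleotide array, giving 1 array per sample. The nontransgenic group held 1 sample. The transgenic group held 3 samples, named A1-3, A1-5 and A19-1, from plants carrying a construct named FCA-csRRM2. FCA is an RNA-binding protein that promotes flowering, and RRM is the usual abbreviation for an RNA recognition motif. The comparison asked which leaf transcripts differed between plants with and without the construct. Of 43603 distinct gene probes, 32589 gave a signal well above background on the nontransgenic array. The corresponding numbers were 33405 on A1-3, 32877 on A1-5 and 33205 on A19-1. The 75th percentile of the processed signal was 1003 on the nontransgenic array, 1344 on A1-3, 1243 on A1-5 and 1208 on A19-1. All levels are log2 values relative to that percentile, and no genome was used here, so positions and exons are not given. With a single control, the spread came from the transgenic arrays alone, and the small number of arrays limited the precision. Nothing in the labels says how separate the transgenic samples were beyond their names, so p-values measured only the spread between these samples.

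The 10 named transcripts with the largest falls included ribosomal proteins L18 and P1-3, the 10 kDa chaperonin and a proton pump subunit. Their names are those of the best match. It was in Medicago truncatula for L18 and the glycosyl transferase, Prunus mume for Pm52, Plantago major for the dehydratase and Arabidopsis thaliana for the others. All 10 were well above background in the nontransgenic leaf, and 9 of them were well above background on no transgenic array. For these 9, the SD and the limma p-value rest on the spread of signals not well above background. Ribosomal protein L18, a component of the large ribosomal subunit, had a level of 2.38 in the nontransgenic sample and −9.06 ± 0.11 (SD, n = 3) in the transgenic samples. It was at least 650-fold lower in the transgenic samples (limma adjusted p = 0.00408). The 60S acidic ribosomal protein P1-3 of the ribosomal stalk was at least 329-fold lower (limma adjusted p = 0.00477), and the Pm52 protein was at least 443-fold lower (limma adjusted p = 0.0134), with another probe of this name passing in the same direction. A family 48 glycosyl transferase, from the family that holds the callose synthases, was at least 210-fold lower. The 10 kDa chaperonin, the partner of the larger chaperonin in protein folding, was at least 284-fold lower. Subunit C of the vacuolar ATP synthase, a proton pump, was at least 155-fold lower. The pleckstrin homology domain-containing protein 1 was at least 136-fold lower, a serine/threonine-protein kinase at least 110-fold lower and a nucleoside-diphosphate-sugar dehydratase at least 70.1-fold lower. The Src2-like protein remained well above background on all 3 transgenic arrays and was 262-fold lower (limma adjusted p = 0.00437). These folds depended on the background correction, since normexp, which adds 50 to every signal and so shrinks the folds of dim probes, gave 48.3- to 103-fold for ribosomal protein L18, 38.4- to 75.7-fold for the Src2-like protein and 7.3- to 13.8-fold for the dehydratase with quantile normalization or with bright local backgrounds replaced. All 10 passed in these 3 settings, whereas none passed under normexp with the 75th percentile and no replacement, without A1-3 or without A1-5, and 8 passed with the A1 samples averaged.

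The 7 named transcripts that rose included glucose-6-phosphate dehydrogenase, glucose-6-phosphate isomerase and another ribosomal L18 transcript. Cytoplasmic glucose-6-phosphate 1-dehydrogenase isoform 2, which starts the oxidative pentose phosphate pathway, was not well above background in the nontransgenic sample and was at least 26.3-fold higher in the transgenic samples (limma adjusted p = 0.03). Glucose-6-phosphate isomerase, an enzyme of glycolysis, was 5.59-fold higher (limma adjusted p = 0.0422). The 60S ribosomal protein L18-2 had a level of −1.93 in the nontransgenic sample and 1.64 ± 0.24 (SD, n = 3) in the transgenic samples, which was 11.9-fold higher (limma adjusted p = 0.0345), and another probe with this name passed in the same direction. N-carbamoylputrescine amidase, an enzyme of polyamine synthesis, was 5.5-fold higher (limma adjusted p = 0.0453). NADH dehydrogenase subunit F was 3.76-fold higher (limma adjusted p = 0.0422). Cytochrome b was at least 2.04-fold higher and a reverse transcriptase-like protein of a non-LTR retrotransposon at least 2.8-fold higher. The best match was in Ichthyophis for cytochrome b, Catanthera pilosa for subunit F, Crucihimalaya himalaica for the isomerase and Arabidopsis thaliana for the others. In the same 3 normexp settings glucose-6-phosphate 1-dehydrogenase differed 3.95- to 6.02-fold, the retrotransposon transcript 1.32- to 1.63-fold and cytochrome b 1.11- to 1.36-fold, and none of these passed (lowest limma adjusted p = 0.117). NADH dehydrogenase subunit F passed in all 3 (2.34- to 2.96-fold), while L18-2 (7.71- to 10.1-fold), the isomerase (2.88- to 3.86-fold) and the amidase (3.68- to 4.79-fold) passed only with backgrounds replaced and the 75th percentile. All 7 calls ended when A1-3 and A1-5, which share the name A1, were averaged (limma adjusted p from 0.106 to 0.259), and when any 1 transgenic sample was left out. Subunit F and the isomerase also lost their calls with median centring (limma adjusted p = 0.0512 and 0.0566), subunit F narrowly without the filter on dim probes, and these 2, L18-2 and the amidase among probes well above background on all 4 arrays (adjusted p from 0.0863 to 0.1). Cytochrome b (0.13) and the retrotransposon transcript (0.0753) lost theirs with the trended, robust variance model. No other named transcript met the criteria for a rise. The next by p were LOC559360 protein (log2 difference 2.04, adjusted p = 0.0791), a probe described as dinitrogenase reductase (at least 13.3-fold higher, adjusted p = 0.0833) and a transporter-like protein (log2 difference 1.45, adjusted p = 0.0889), none of which passed limma's test.

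**Figure D1:**
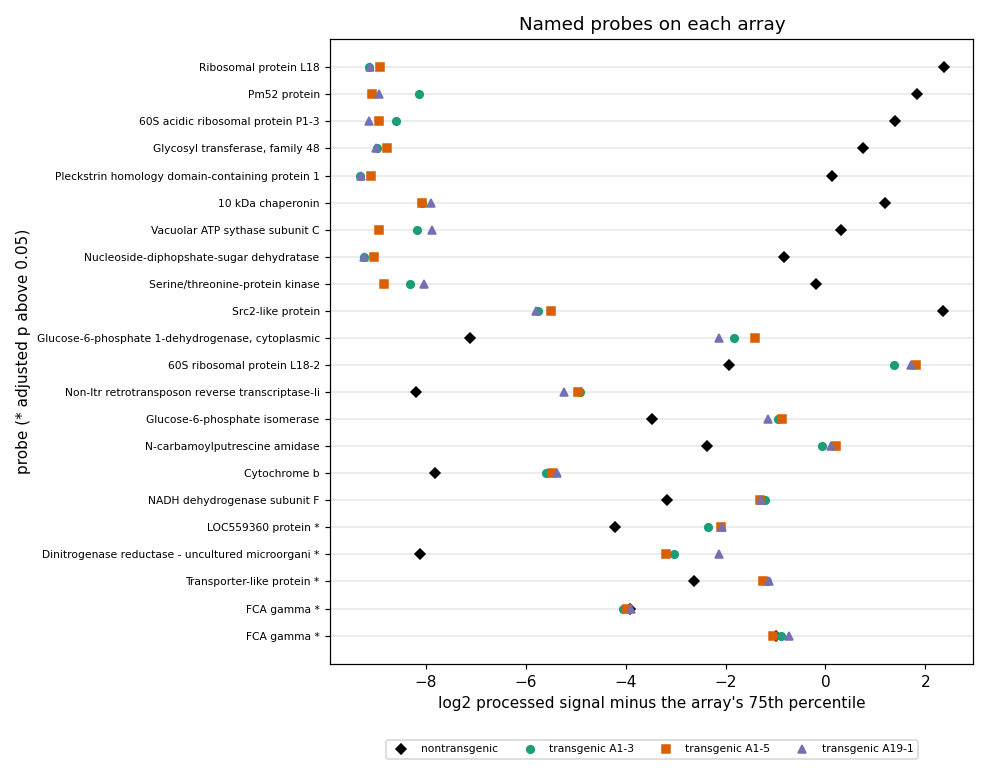
Level of each named probe on each array, as log2 processed signal minus the array's 75th percentile, with 1 symbol per array. The 10 lower probes at the top have their nontransgenic diamond to the right of the transgenic symbols, the 10 higher probes have it to the left, and for both FCA gamma probes the 4 symbols nearly coincide.

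In all, 272 of 34827 tested probes passed an adjusted p of 0.05 in limma, of which 246 were lower and 26 higher in the transgenic samples. Only 66 of the 272 had a description naming a gene or protein. Of the 246 lower probes, 191 were not well above background on any transgenic array, and with 1 control these differences may belong to that sample and not to its genotype. For these 191, the spread behind the p-value was that of signals not well above background. Probes at least 16-fold lower than the control in every transgenic array numbered 177, and 150 of these passed the test, while 17 probes were at least 16-fold higher in every transgenic array. When each transgenic array in turn was set against the other arrays in the same way, 0 probes passed for each of them by limma, with 1043, 744 and 3625 probes at an unadjusted p under 0.05 for A1-3, A1-5 and A19-1, against 3585 for the nontransgenic array. The control was then among the other arrays, and probes that set it apart widened the spread, so these numbers are not like for like. On simulated arrays of the same design, changes were placed only on probes of intermediate level. There limma recovered 82.5% of 16-fold changes, 5.37% of 4-fold changes and 0.152% of 2-fold changes, so smaller differences were mostly not detectable. False calls averaged 6.4 per run, a larger share of all calls than the threshold of 0.05. The count fell to 0 without A1-3 and 0 without A1-5, was 160 without A19-1, and was 15 among probes well above background on all 4 arrays.

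**Figure D2:**
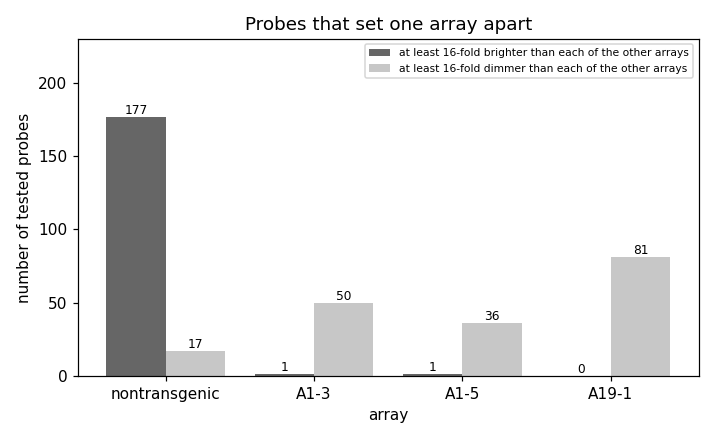
Number of tested probes at least 16-fold brighter (dark bars) or dimmer (light bars) on the named array than on each of the other 3 arrays. The nontransgenic array had 177 brighter and 17 dimmer probes, while each transgenic array had at most 1 brighter probe and 36 to 81 dimmer probes.

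At a 2-fold threshold without a test, 913 probes (2.62% of those tested) were lower and 490 (1.41%) were higher than the control in every transgenic array. Unchanged arrays sharing 1 control gave on average 217.6 lower and 217.7 higher probes in 100 simulations, with at most 255 lower and 260 higher. A19-1 set apart exceeded these numbers too, being at least 2-fold below each other array at 741 probes and above each at 353. A1-3 was below at 344 and above at 200, and A1-5 at 263 and 222. A number above the simulated ones thus does not by itself mark an effect of the construct. The excess of lower probes depended on the scaling, with 857 lower and 609 higher under quantile normalization and 794 lower and 687 higher under spike-in scaling. Among probes well above background on every array, 447 were lower and 275 higher. Without A1-3, 1121 were lower and 753 higher, but with fewer arrays to meet the threshold both counts could only rise.

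The list of cell wall loosening and expansion genes, fixed before the data were examined, held 2 members that fell, and as a list it passed camera as lower only with the correlation preset. The fasciclin-like arabinogalactan protein 2, a cell surface glycoprotein, fell from 0.39 to −5.55, a log2 difference of −5.93 ± 0.19 (SE, limma adjusted p = 0.00752). An extensin, a structural wall protein, fell from −4.41 to −6.26, a log2 difference of −1.85 ± 0.14 (SE, limma adjusted p = 0.0458). These were the only members of the list to pass over all probes, whereas adjusted over the list alone 4 members were lower and 1 was higher. Of 101 tested members, 77 lay below the control and 24 above it, and 48 were below it in every transgenic array against 13 above it in every one. The median log2 difference was −0.29, and the list passed camera with a preset correlation of 0.01 (adjusted p = 6.14e-05). With an estimated correlation, which leaves the test 2 degrees of freedom, adjusted p = 0.923, and fry gave an adjusted p = 0.234. The preset correlation also passed 5 lists when A1-3 was set apart from the other arrays, 2 for A1-5 and 5 for A19-1. Some of these calls may mirror an array left among the others. Histones, called for A1-5, had a median level of 1.93 on A1-5, 1.93 on A1-3, 1.87 on the control and 1.4 on A19-1. A polygalacturonase, a pectin-degrading enzyme, had the lowest p among members above the control (log2 difference 2.85, limma adjusted p = 0.0941) and did not pass. Cellulose and secondary wall genes had a median log2 difference of −0.16 over 32 probes (camera adjusted p = 0.0603). Among them a cinnamoyl CoA reductase-like protein, named for an enzyme of lignin synthesis, was at least 16.2-fold lower (limma adjusted p = 0.00816), while cellulose synthase A catalytic subunit 3 differed by 0.25 ± 0.14 (SE) on the log2 scale (limma adjusted p = 0.628).

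Genes of light harvesting and the photosystems also lay below the control, but 34 of the 61 tested probes were saturated on at least 1 array and 31 on all 4. The median log2 difference was −0.32 over all 61 probes and −0.14 over the 27 probes saturated on no array. Probes of any kind saturated on all 4 arrays had a median log2 difference of −0.34. With A19-1 set apart from the other arrays, 55 of the 61 probes were lower on it (median −0.05, camera adjusted p = 0.0108, and 0.775 with an estimated correlation). Those arrays include the control. The list's median level was 5.63 on A19-1, 5.44 on A1-3, 5.58 on A1-5 and 5.91 on the control. With 31 of the 61 probes saturated on all 4 arrays, these medians lie at or near the ceiling. They ran in the reverse order of the log2 percentile subtracted, which was 10.239, 10.392, 10.28 and 9.971 on the same arrays. They thus do not rank transcript levels, and the call for A19-1 may restate the control's higher scaled values. The list passed camera at the preset correlation (adjusted p = 1.41e-07) but not without probes saturated on any array, an alternative chosen after the data were seen (adjusted p = 0.342), nor with quantile normalization (adjusted p = 0.0782). With an estimated correlation adjusted p = 0.923. No member passed limma's test, the lowest p being that of photosystem I subunit III, with a log2 difference of −6.96 ± 2.08 (SE, adjusted p = 0.439). Carbon fixation genes, of which 12 of 24 probes were saturated on at least 1 array, had a median of −0.22 over all and 0.1 over the unsaturated members (camera adjusted p = 0.0748). In chlorophyll and carotenoid synthesis, lycopene epsilon cyclase differed by 1.12 ± 0.16 (SE) on the log2 scale without passing (limma adjusted p = 0.174), and the list's camera adjusted p was 0.591.

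Flowering, cell cycle and hormone lists did not pass camera. Of 24 tested flowering time probes, 16 lay above the control and 8 below, with a median log2 difference of 0.16 (camera adjusted p = 0.402). A CONSTANS homolog, related to a regulator of photoperiodic flowering, differed by 1.51 ± 0.33 (SE) on the log2 scale without passing (limma adjusted p = 0.318). Cyclin-B2-1, a mitotic cyclin, was the only cell cycle member to pass and was at least 7.33-fold lower (limma adjusted p = 0.0415), while the list of 38 probes had a median of −0.01 (camera adjusted p = 0.608). Cyclin-D3-1 differed by −0.89 ± 0.25 (SE, limma adjusted p = 0.417). No member of the auxin, gibberellin and brassinosteroid, or cytokinin and organ growth lists passed, and their camera adjusted p-values were 0.815, 0.574 and 0.846. An auxin-responsive GH3 family protein showed log2 differences of 2.81 on one probe and −3.18 on another probe with the same description, neither passing (limma adjusted p = 0.135 and 0.358). Circadian clock genes had a median of 0.02 over 7 probes (camera adjusted p = 0.815).

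Ribosomal protein transcripts changed in both directions. Of 424 tested probes, 6 passed as lower and 2 as higher, and the median log2 difference was −0.03 (camera adjusted p = 0.594). The chloroplast 30S ribosomal protein S3, whose best match was in the green alga Staurastrum punctulatum, was at least 60.4-fold lower (limma adjusted p = 0.0041), in addition to the L18 and P1-3 transcripts. RNA binding and splicing genes included no member that passed among 114 probes (median −0.02, camera adjusted p = 0.815). A protein with an RNA recognition motif differed by −0.61 ± 0.16 (SE, limma adjusted p = 0.404), and splicing factor RSZ33 by 0.7 ± 0.2 (SE, limma adjusted p = 0.42). Histones had a median of −0.12 over 86 probes (camera adjusted p = 0.594). Among 38 transposable element probes, only the non-LTR retrotransposon transcript passed, and the list's camera adjusted p was 0.815.

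The oxidative stress, heat shock and defence lists held 1 or 2 transcripts each that fell, and no stress list passed camera. Superoxide dismutase [Cu-Zn], which removes superoxide, fell from 5.19 to −1.14 on the log2 scale, a difference of −6.34 ± 0.25 (SE, limma adjusted p = 0.0113). It was the only one of 130 oxidative stress probes to pass (camera adjusted p = 0.402). In the heat shock and chaperone list, 2 of 109 probes passed, both lower (camera adjusted p = 0.594). A disease resistance protein-like transcript was at least 2.05-fold lower (limma adjusted p = 0.0192), and the salicylate and defence list had a median of −0.06 over 74 probes (camera adjusted p = 0.594). No member of the cold and dehydration, jasmonate or glucosinolate lists passed. Cold-regulated protein Cor25 differed by 1.6 ± 0.17 (SE) on the log2 scale without passing (limma adjusted p = 0.103). The jasmonate list had a camera adjusted p of 0.776 and the glucosinolate list 0.402. In starch and sugar metabolism, granule bound starch synthase differed by −2.04 ± 0.33 (SE, limma adjusted p = 0.226), and the list's camera adjusted p was 0.594.

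No list of markers of other organs passed camera, although single members fell. Napin-B, a seed storage protein, had a level of −5.56 in the nontransgenic sample and was at least 2.65-fold lower in the transgenic samples (limma adjusted p = 0.0304). The seed list of 7 probes, 1 of which matched only because its description names a 12S ribosomal RNA, had 6 members below the control and a log2 difference of −0.09 by median and −0.78 by mean (camera adjusted p = 0.0615). SCARECROW, a regulator of root and leaf tissue patterning, was at least 14.1-fold lower (limma adjusted p = 0.00549), and the root list's camera adjusted p was 0.846. Napin-B and SCARECROW were well above background on no transgenic array, so their limma p-values rest on the spread of such dim signals. No marker of flower, anther and pollen or of meristem and stem passed, and camera adjusted p was 0.574 and 0.402. Ribosomal RNA and organelle transcripts, read as signs of RNA quality, had a median of −0.19 over 25 probes, 7 of them saturated on all 4 arrays, and 0.07 over the 18 unsaturated ones (camera adjusted p = 0.402). Senescence genes had a median of 0.18 over 18 probes (camera adjusted p = 0.402). Of all 32 lists tested, 30 did not pass camera, with adjusted p from 0.0603 to 0.973. Median and mean log2 differences had opposite signs for chlorophyll and carotenoid synthesis (0.11 and −0.1), root markers (0.08 and −0.05) and cold and dehydration (0.01 and −0.02), and camera's direction was up for each. For fatty acid and lipid synthesis camera's direction was up with a median of −0.04, and fry's direction was opposite to camera's for the auxin, transposable element and root lists. With an estimated correlation none passed, and with fry none passed, while fry's mixed test passed 16 of the 32 lists, among them cell wall loosening (adjusted p = 0.000971). Of 163 description words tested in both directions by Fisher's exact test, none was enriched, the lowest adjusted p being 0.246 for glucose among higher probes, with 2 of 8 named higher probes against 41 of 7723 tested.

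**Figure D3:**
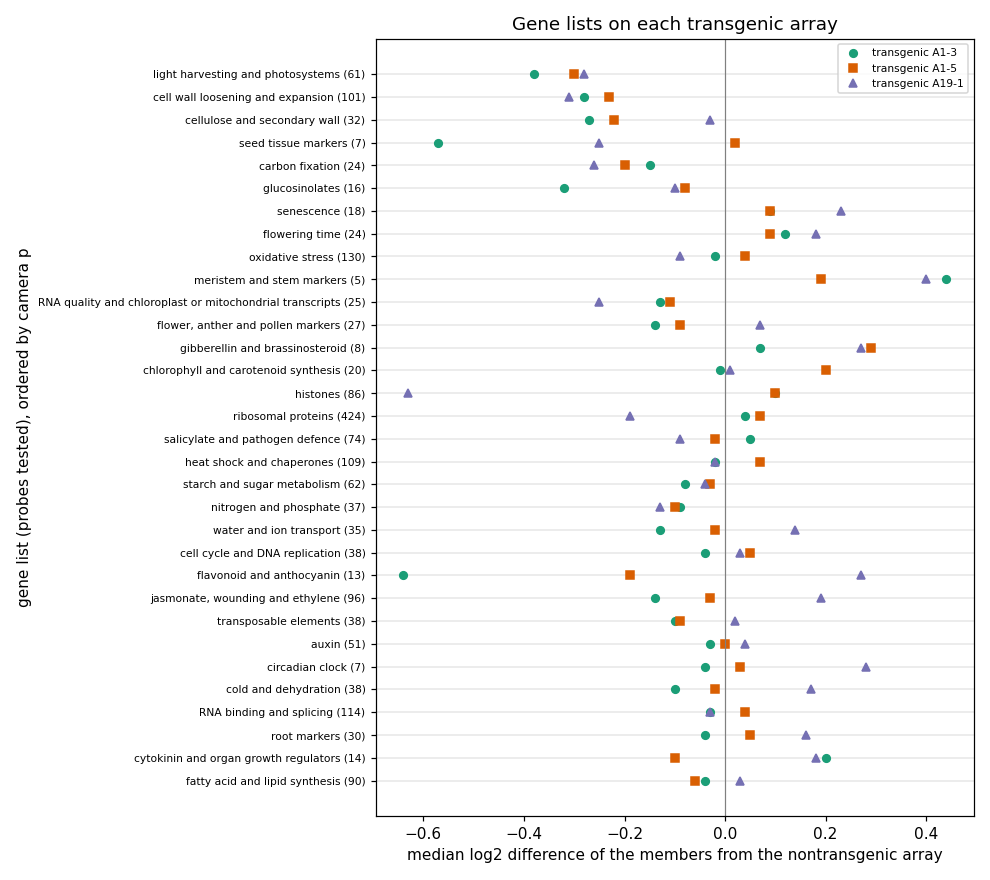
Median log2 difference of each gene list's tested probes from the nontransgenic array, 1 symbol per transgenic array, with the number of probes in brackets and lists ordered by camera p. The cell wall loosening and the light harvesting lists lie below 0 on all 3 transgenic arrays.

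The transgenic samples also differed among themselves. A1-3 and A1-5 differed at least 2-fold at 1948 probes, A1-3 and A19-1 at 3295, and A1-5 and A19-1 at 2959. Against the control, the counts were 3493 for A1-3, 3245 for A1-5 and 4284 for A19-1. Ratios to the shared control correlated across probes, which are not independent replicates, with r = 0.719 for A1-3 with A1-5, 0.613 for A1-3 with A19-1 and 0.61 for A1-5 with A19-1. Unchanged arrays sharing a control gave 0.506 in simulation. The covariances were 0.673, 0.629 and 0.597 in the same order, against 0.211 in simulation. The simulated control varied like the transgenic arrays, so part or all of the excess may come from the shared control.

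Both probes described as FCA gamma gave nearly equal levels in all samples after 75th percentile scaling of the processed signals. The probe with the sequence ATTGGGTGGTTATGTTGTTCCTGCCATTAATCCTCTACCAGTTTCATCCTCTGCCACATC had a level of −3.92 in the nontransgenic sample and −4.05, −3.98 and −3.89 in A1-3, A1-5 and A19-1. The log2 difference was −0.06 ± 0.15 (SE, limma adjusted p = 0.929), and it was 0.05 with quantile normalization and 0.08 with spike-in scaling. Under normexp with the 75th percentile it was 0.67, and −0.12 with bright local backgrounds replaced. The probe with the sequence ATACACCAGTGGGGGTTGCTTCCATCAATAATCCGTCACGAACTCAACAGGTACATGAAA had a level of −1 in the nontransgenic sample and −0.9, −1.06 and −0.74 in the transgenic samples, a log2 difference of 0.1 ± 0.19 (SE, limma adjusted p = 0.905). Whether either sequence lies in the part of FCA carried by the construct is not given, so neither probe checks the presence of the transgene.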

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

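The tests without saturated probes, with spike-in scaling and with replaced local backgrounds were chosen after the data were seen. The count of 272 differing probes (26 higher, 246 lower) stayed within 1.5 times under quantile or median normalization, the series matrix, no filter, a 2-fold minimum, 1 probe per gene, spike-in scaling and without saturated probes, although the higher count was 17 with 1 probe per gene. It was 150 (16 higher, 134 lower) with a trended, robust variance model, 46 (0 higher, 46 lower) with the A1 samples averaged, and 15 (1 higher, 14 lower) among the 31214 probes well above background on all 4 arrays, where 58 of the 272 could be tested. Leaving out 1 transgenic sample gave 0 to 160 probes, 0 to 6 higher and 0 to 154 lower. Without A1-3 the count was 0 with 2538 probes at an unadjusted p under 0.05, and without A1-5 it was 0 with 2471, both by limma with 1 residual degree of freedom. Without A19-1 it was 160, of which 100 were among the 272. Normexp with the 75th percentile gave 0 probes (0 higher, 0 lower), with 192 at an unadjusted p under 0.05, and normexp with quantile normalization gave 158 (4 higher, 154 lower). A1-3 had 26 local backgrounds above 50, no other array had any, and normexp raised the lower quartile of A1-3 to 10.11 against 6.17 on the control. With these replaced the lower quartile was 6.2 and the counts were 211 (16 higher, 195 lower) and 162 (4 higher, 158 lower), so the count of 0 came from these spots. The probes 2-fold higher in every transgenic sample (490) and lower (913) were 160 and 187 under normexp with the 75th percentile, 93 and 356 under normexp with quantile normalization, 127 and 518 or 153 and 451 with backgrounds replaced, and 275 and 447 among probes well above background on all 4 arrays. Without 1 transgenic sample, when fewer arrays had to meet the threshold, the higher count ranged from 690 to 753 and the lower from 1121 to 1293. The median log2 difference of all probes was 0.32 under normexp with the 75th percentile and 0.16 under spike-in scaling, against 0.02.

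The number of gene lists past the threshold, 2, was 8 under normexp with the 75th percentile, 1 under normexp with quantile normalization, 4 with median centring, 4 with the trended variance model, 4 with spike-in scaling, 1 without saturated probes, 0 with an estimated correlation and 0 with fry. The cell wall list kept its direction and passed in all other settings, with adjusted p = 0.923 with an estimated correlation and 0.234 with fry. The light harvesting list did not pass with quantile normalization (0.0782), the series matrix (0.118), normexp with quantile normalization (0.358, or 0.359 with backgrounds replaced), without saturated probes (0.342), with an estimated correlation (0.923) or with fry (0.47). Of the 17 named probes that passed, none reversed its direction, while 17 no longer passed without A1-3, 17 without A1-5, 10 without A19-1, 9 with the A1 samples averaged, 17 under normexp with the 75th percentile (3 with backgrounds replaced), 6 under normexp with quantile normalization (6 with backgrounds replaced), 2 with median centring, 2 with the trended variance model and 1 without the filter. Among probes well above background on all 4 arrays, 4 lost the call. Of the rest only the Src2-like protein could be tested there, and it kept its call. The log2 differences of the 17 named probes moved by at most 0.3 when 1 sample was left out. Ribosomal protein L18 (−11.44) was −11.41 without A1-3 and −11.51 without A1-5, but −5.48 under normexp with the 75th percentile. For probes well above background on no transgenic array, such small shifts are those of signals near background. Apart from the normexp count, the cause of these differences was not tested. No paired analysis was possible because the groups share only the number 1, which does not mark a common origin.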

Other observations

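Beyond the comparison with the control, histones set A19-1 apart from the other samples. Of 86 tested histone probes, 70 were lower on A19-1 than the mean of the other 3 arrays, and the median log2 difference was −0.71. The median level of the list was 1.4 on A19-1, against 1.93 on A1-3, 1.93 on A1-5 and 1.87 on the nontransgenic array. Camera gave an adjusted p of 7.8e-17 at the preset correlation and 0.737 with an estimated correlation. Ribosomal proteins were lower on A19-1 too, with 333 of 424 probes below the mean of the other arrays (median −0.22, camera adjusted p = 5.36e-10, and 0.737 with an estimated correlation). On A1-3, 12 of 13 flavonoid and anthocyanin probes were lower than the mean of the other arrays (median −0.65, camera adjusted p = 0.000173, and 0.796 with an estimated correlation). On A19-1, 11 of the 13 were higher (median 0.6, camera adjusted p = 0.00802, and 0.765 with an estimated correlation). The median level of this list was 0.46 on A1-3, 0.2 on A1-5, 0.78 on A19-1 and 0.5 on the nontransgenic array. These comparisons were made after the data were seen, and the preset correlation thus called lists for single transgenic samples as it did for the control. Some of these calls may mirror another array left in the mean of the others.

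The tests on transcripts at least 16-fold lower and on saturated light harvesting probes, and the count of probes with other arrays set apart, were chosen after the results were seen, and the 2 cell wall tests that leave out probes were moved from p to adjusted p after theirs. The first pattern was the 177 probes at least 16-fold lower in every transgenic sample. A fault of single spots or probes is argued against by the other probes of the same target identifiers, where there were any. Of these, 65% (13 of 20, exact 95% interval 40.8% to 84.6%) were at least 4-fold lower in every transgenic sample, against 1.21% of all tested probes. The 20 probes belong to only 13 targets and were counted as independent. The check covers these targets and not the rest of the 177 probes. RNA of another plant in the nontransgenic sample stays open, since best matches outside the Brassicaceae were 1.39 times as likely by odds ratio as among comparably bright probes (52% against 43.7%, 95% interval 0.862 to 2.26). A switch to other copies of the same gene, with 1 of 50 named probes having a same-description probe at least 2-fold higher against a median of 1 in 10000 random draws, stays open too. Only identical descriptions were paired, so ribosomal protein L18, which fell, was not set against L18-2, which rose. In the 1 pair counted, of an aspartic protease, neither probe passed (limma adjusted p = 0.208 for the lower and 0.429 for the higher). A heritable difference between the plants that goes with the construct or with the lines cannot be separated with 1 control and was not tested. Nor can a difference of the genotype be told from one of that single control sample, which stays open for all 246 lower probes.

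The second pattern was the lower light harvesting list. Saturation accounts for part of it, since probes saturated on all 4 arrays share a ceiling and differed by a median of −0.34 after scaling. The log2 75th percentile subtracted exceeded the control's by 0.421 on A1-3, 0.309 on A1-5 and 0.268 on A19-1. A spot at the ceiling on every array falls by these amounts, so the 31 members saturated on all 4 arrays do not measure a change. The 27 members saturated on no array had a median of −0.14, between the values that would have decided it. Whether their transcripts were lower stays open. The list was also called lower on A19-1 set apart (camera adjusted p = 0.0108, and 0.775 with an estimated correlation), but the control was among the arrays it was set against. The list's medians on A19-1 (5.63), A1-3 (5.44) and A1-5 (5.58) lie at or near the ceiling and do not rank transcript levels. This call is thus not separate evidence.

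The third pattern was the cell wall list, called lower at the preset correlation only. Only 1 of 101 members was saturated, and camera gave an adjusted p of 8.41e-05 at the preset correlation without saturated probes. In the same setting camera gave an adjusted p of 0.000113 over the 99 members left without probes that changed 16-fold. So few members were left out that these tests could hardly have ended the call. They show only that the call at the preset correlation did not rest on these members. With each array set apart in turn, 1 of 4 arrays, the control, gave a p as small as 3.84e-06, and the smallest of the others was 0.021. In the same way 1 array of 4 gave as many as 272 differing probes, and the highest of the others was 0. With 4 such splits no share under 0.05 can be had. When a transgenic array was set apart, the control was among the other arrays and widened their spread at probes that differ on it. These splits are therefore not like for like.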
